A study of Mus musculus with 12 samples.

How the data were processed

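Total RNA from 12 mouse samples in 4 groups of 3 was measured on Affymetrix mouse expression arrays. The groups were unstimulated RAW264.7 cells, RAW264.7 cells cultured with estradiol at 1 ug/mL overnight, bronchoalveolar lavage (BAL) macrophages of control mice, and BAL macrophages of pregnant mice. RAW264.7 is a mouse macrophage-like line established from a male animal, and bronchoalveolar lavage washes free cells out of the airways and alveoli. Per the labels' protocols, RNA was extracted with silica columns and DNase digestion and labelled with biotin. The series' design text states that lavage cells went straight to RNA extraction and that the untreated RAW264.7 cultures received vehicle, whereas the sample labels call them unstimulated. The treatment text in the labels, estradiol overnight, is attached to every sample, the lavage samples included, which conflicts with the design text for those samples. Groups were taken from the group label alone. The labels do not name the vehicle, the stage of pregnancy, the sex of the control mice, or any sorting of the lavage cells. Replicates were numbered in deposit order only, so no samples were paired across groups, and the labels do not say whether replicates came from separate cultures, animals or pools. The p-values therefore measure only the spread between these samples, which may be partly technical.

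The deposited table holds one linear intensity per probe set and array, from 6.51 to 28506. Per the submitters' processing notes the values were made with RMA (background correction, quantile normalization and summary of probes), with no version stated. RMA normally gives log2 values. The planned design assumed that scale and named log2(value + 1) for the case of linear values, which was used here. A fold change below is therefore on the log2(value + 1) scale, which slightly understates changes of dim genes. The deposited table holds no detection calls. As a marker of dim signal, a gene is called dim below when it lay above its array's 40th percentile on fewer than 3 of the 6 arrays compared. For arrays, their number limits the precision.

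There were 22690 probe sets. Of these, 20380 were paired with 1 gene symbol, 691 with several and 1555 with none, and 64 control probe sets were left out. Probe sets were named through the platform annotation supplied with the data, and 29 single-gene probe sets had an Entrez ID without a match in the current gene table, so their symbols stayed as listed. No listed symbol was replaced. Of several probe sets of a gene (4956 genes), the one with the highest mean over all arrays was kept, which left 12393 genes. No pair of arrays had identical values. Genomic positions were not analysed here, since no genome build is given in the sources used here.

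Each comparison was fitted in limma 3.58.1 under R 4.3.3 (lmFit and eBayes with a constant prior). The estradiol, pregnancy and source comparisons each used the 6 arrays compared, and the difference between the estradiol and pregnancy changes used all 12. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 12393 genes, and a gene was called at an adjusted p under 0.05. The estradiol and pregnancy comparisons each tested 35 gene lists (pathways, handling and quality genes, markers of cell types) with limma's camera at its preset inter-gene correlation of 0.01, again adjusted by Benjamini-Hochberg. Of 713 list entries, 625 were measured. Other tools used were the R package data.table (version 1.17.8) and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

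The groups, tests, lists, alternatives and naming rule were set before the data were examined. The rule names, per comparison, up to 10 called genes with the largest rise and 10 with the largest fall whose groups did not overlap, leaving out predicted genes, or the 10 smallest p-values where fewer than 5 genes passed. It adds the nitric oxide synthases and the estrogen and progesterone receptors, up to 4 members of each called list by smallest p, up to 2 called members of each other list, and 10 genes with the largest difference between the 2 changes. Gper1, also in the rule, was not analysed here because no single-gene probe set was paired with it.

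The alternatives were quantile normalization, a shift of arrays to a common median, a filter that kept genes above the 40th percentile on at least 3 arrays, the mean of a gene's probe sets, an intensity-dependent robust prior, array weights, all 12 arrays in one fit, all probe sets, a fold threshold of 2, an adjusted p threshold of 0.01, camera with an estimated correlation, the rotation test fry, and each array left out in turn. Camera asks whether a list shifted against the other genes, whereas fry asks whether its members changed at all. Fry can therefore call a list that moved no more than the rest. Leaving out the pseudocount was added after seeing the data. The fits were tested on simulated data made from the real means and spreads of the 12393 genes, with 200 changed genes in each of 10 runs. Noise was normal, drawn for each gene alone and with the same spread in every group. The rates below therefore cover neither correlation between genes nor groups of unequal spread. Pearson correlations between real arrays were 0.9988 to 0.9990 among unstimulated and 0.9957 to 0.9984 among estradiol RAW264.7 samples. In the estradiol comparison 76.8% of 1.5-fold and 94.4% of 2-fold changes were recovered, with 4.94% false calls. For pregnancy the values were 59.8%, 84.2% and 4.72%, for the source comparison 70.5%, 89.0% and 5.54%, and for the difference 56.1%, 84.9% and 4.69%.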

Results

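The series asks how estradiol acts on mouse alveolar macrophages and on RAW264.7 cells, through estradiol given to the cell line and through pregnancy in mice. The median intensity of the 12 arrays lay between 369 and 393. Pearson correlations of log2 values were 0.995 to 0.999 between arrays of a group and 0.912 to 0.919 between the cell line and the lavage samples. Between estradiol and unstimulated RAW264.7 arrays they were 0.994 to 0.997, and between pregnant and control lavage arrays 0.993 to 0.997. These ranges overlap those within groups. One cell-line array stood apart in RNA quality. Estradiol replicate 2 had a 3' to 5' difference of 0.74 (log2) for actin, against 0.39 to 0.48 on the other RAW264.7 arrays, and of 4.31 against 3.16 to 3.43 for the transferrin receptor. Among the lavage arrays pregnant replicate 2 had the highest differences. They were 0.39 against 0.26 to 0.35 for actin and 3.86 against 2.83 to 3.47 for the transferrin receptor. Sex-linked transcripts separated the sources. Xist, the RNA that silences an X chromosome in female cells, averaged 5.30 ± 0.33 (SD, n = 3, log2) in unstimulated RAW264.7 cells and 12.52 ± 0.11 in control lavage cells, while Y-linked Eif2s3y averaged 12.45 ± 0.02 and 3.68 ± 0.09. Kdm5d and Uty, also Y-linked, were likewise high in RAW264.7 cells (9.66 and 8.99) and low in control lavage cells (3.98 and 3.78). Pregnant lavage samples resembled the control ones, with Xist at 12.36 ± 0.18 and Eif2s3y at 3.79 ± 0.21. By these transcripts the lavage samples of both groups had the pattern of female cells.

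In RAW264.7 cells given estradiol at 1 ug/mL overnight, genes of the NF-kB inflammatory list were higher and genes of cholesterol synthesis lower than in unstimulated cells (3 treated against 3 unstimulated arrays). Cxcl2, a chemokine that draws neutrophils, rose by a log2 fold change of 2.22 ± 0.06 (SE, 4.67-fold, limma adjusted p = 3.5e-05). Ptgs2, the inducible cyclooxygenase, rose 3.70-fold, and Arg2, the mitochondrial arginase, 3.88-fold. The C-type lectin receptor Clec4n rose 5.34-fold. The largest fall was that of Cyp2s1, a cytochrome P450 enzyme, by 3.36 ± 0.10 on the log2 scale, which is 10.3-fold lower (limma adjusted p = 3.6e-05).

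Other large rises were those of Crip2 (5.56-fold), the extracellular sulfatase Sulf2 (4.85-fold), the RNA-binding protein gene Celf4 (6.59-fold), Lcn2, an iron-sequestering lipocalin (4.23-fold), the gap junction gene Gja1 (3.87-fold) and the carboxylesterase Ces2g (3.70-fold). Celf4, Lcn2, Gja1 and Ces2g, and Dkk2 below, were dim, and 1 of the 6 probe sets of Gja1 had a log2 change of -0.09. Large falls included H2-Ea, an MHC class II chain (3.81-fold lower), Rtp4, an interferon-induced gene (3.62-fold lower), Ms4a4c (3.28-fold lower), the receptor Gpr34 (3.23-fold lower), the Wnt antagonist Dkk2 (3.22-fold lower), H2-Aa (2.67-fold lower) and Calml4 (2.66-fold lower). Another H2-Ea probe set changed by 0.08. H2-T24, an MHC class I gene, was 3.35-fold lower, and its limma adjusted p went from 0.0113 to 0.0526 without unstimulated replicate 2.

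The NF-kB inflammatory list rose as a group. Of its 27 measured genes, 16 rose and 0 fell (18 and 0 adjusted over the list alone), with a median log2 change of 0.49 (camera adjusted p = 2.0e-12, and adjusted p = 0.0354 with an estimated correlation). Besides Cxcl2 and Ptgs2 these included Csf1, the macrophage growth factor (log2 1.74 ± 0.09, dim), and the signalling adaptor Traf1 (1.21 ± 0.06). The list of cholesterol synthesis and uptake genes, driven by the transcription factor SREBP2, fell. Of 18 measured genes 17 fell and 0 rose (18 and 0 adjusted over the list alone), with a median of -0.75 (camera adjusted p = 1.2e-20, and adjusted p = 0.0325 with an estimated correlation). Mevalonate pathway enzymes were among them, with Pmvk at -1.11 ± 0.05, Mvk at -0.95 ± 0.06, the squalene synthase Fdft1 at -0.89 ± 0.05 and the sterol reductase Tm7sf2 at -0.98 ± 0.05. One of the 4 Fdft1 probe sets changed by 0.01. Each of these lists kept its call without any 1 array. Handling cannot be told apart from estradiol in these samples, since each culture condition held 1 group. Solvent cannot either if the untreated cultures had none, as the label unstimulated may mean. If they received vehicle, as the design text states, solvent would be shared by both groups.

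Other lipid lists also fell. Of 14 genes targeted by the sterol-sensing receptor LXR, 6 fell and 0 rose (8 fell and 1 rose adjusted over the list alone), with a median of -0.23 (camera adjusted p = 5.2e-05, and adjusted p = 0.0899 with an estimated correlation). The cholesterol exporter Abca1 was at -0.71 ± 0.07 and Mylip, a ligase that degrades the LDL receptor, at -0.48 ± 0.05. Of 15 PPAR target and lipid-handling genes, 6 fell and 0 rose, with the same counts adjusted over the list alone and a median of -0.24 (camera adjusted p = 0.00147, and adjusted p = 0.234 with an estimated correlation). Hadha, an enzyme of fatty acid oxidation, was at -0.29 ± 0.05 and the lipid carrier Fabp4 at -0.25 ± 0.04. Without unstimulated replicate 2 the list's median was -0.14, and with the mean of all probe sets -0.16. The calls of both genes ended without unstimulated replicate 1 (adjusted p = 0.0722 and 0.0702), replicate 2 (0.0729 and 0.0677) or replicate 3 (0.0702 and 0.0660).

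Some stress-response lists rose and others were not called by camera. In the list of ATF4 and unfolded protein response genes, which act when protein folding or amino acid supply is disturbed, 12 of 24 genes rose and 0 fell (13 rose and 1 fell adjusted over the list alone). Its median was 0.21 (camera adjusted p = 1.1e-05, and adjusted p = 0.0899 with an estimated correlation), and Ddit4 (1.10 ± 0.08), Sesn2 (1.01 ± 0.07), Herpud1 (0.64 ± 0.05) and Ddit3 (0.60 ± 0.05) led it. Of 20 immediate early genes, which respond to many stimuli and to handling, 8 rose and 1 fell (12 and 2 adjusted over the list alone; median 0.20; camera adjusted p = 0.000713, and adjusted p = 0.348 with an estimated correlation). Ier3, Nr4a1 and Btg2 rose by 1.03 ± 0.08, 0.88 ± 0.07 (dim) and 0.87 ± 0.06, and the transcription factor Klf2 fell by 1.05 ± 0.09. Of 19 NRF2 antioxidant genes 4 rose and 1 fell (5 and 2 adjusted over the list alone), and of 16 heat shock genes 1 rose and 0 fell, with the same counts adjusted over the list alone. Camera called neither list (adjusted p = 0.380 and 0.276), while fry called both upward (adjusted p = 0.00949 and 0.0047). The fry calls do not show that these lists moved more than other genes.

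Glucocorticoid-responsive genes rose in 8 of 20 cases and fell in 1 (9 and 1 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.0347, and adjusted p = 0.234 with an estimated correlation). The cell cycle inhibitor Cdkn1a (0.81 ± 0.05) and the metallothionein Mt2 (0.69 ± 0.04) rose. Ddit4, named above in the ATF4 list, is also in this list. The list's call ended without estradiol replicate 1 (adjusted p = 0.0845), without estradiol replicate 3 (0.0846) and with the mean of all probe sets (0.0759, median 0.07). Of 11 SOCS and STAT5 target genes 4 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 0.0163, and adjusted p = 0.234 with an estimated correlation). Among them was Ccnd2, a cyclin (0.49 ± 0.08), and the call ended without estradiol replicate 3 (0.0747). With the mean of all probe sets its median was 0.15. Of 14 dendritic cell and monocyte markers 5 rose and 0 fell, with the same counts adjusted over the list alone and a median of 0.13 (camera adjusted p = 0.0264, and adjusted p = 0.234 with an estimated correlation). The transcription factor Zbtb46 was at 1.08 ± 0.10, with 1 of its 3 probe sets at -0.32, and the chemokine receptor Cx3cr1 at 0.62 ± 0.07. Without estradiol replicate 2 the adjusted p of this list was 0.0588.

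The type I interferon list went both ways and fell on balance. Of 23 genes 10 fell, among them Rtp4 and the antiviral enzyme Oas1a (-0.53 ± 0.07), and 3 rose, with Gbp2 at 1.07 ± 0.13 and Cxcl10 at 0.59 ± 0.06, both dim (13 fell and 5 rose adjusted over the list alone). The median was -0.33 (camera adjusted p = 0.00352, adjusted p = 0.464 with an estimated correlation, and 0.0532 with fry). Cell cycle genes fell slightly, 7 of 31 with 0 rises (13 fell and 1 rose adjusted over the list alone), with a median of -0.11 (camera adjusted p = 8.6e-05, adjusted p = 0.464 with an estimated correlation, and 0.0532 with fry). Without estradiol replicate 2 its median was -0.19. Cdc20, an activator of mitotic exit, was at -0.26 ± 0.04. Its call ended without unstimulated replicate 1 (adjusted p = 0.0542), replicate 2 (0.0644) or replicate 3 (0.0689), and with the mean of its probe sets (0.247).

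Energy metabolism lists fell by small amounts. Of 27 oxidative phosphorylation genes 3 fell and 0 rose (0 and 0 adjusted over the list alone), with a median of -0.08 (camera adjusted p = 0.000167, and adjusted p = 0.348 with an estimated correlation). Sdhc, a subunit of succinate dehydrogenase, was at -0.18 ± 0.04, and its call held only with all arrays or without estradiol replicate 2. It ended without unstimulated replicates 1, 2 and 3 (adjusted p = 0.164, 0.150 and 0.140) and without estradiol replicates 1 and 3 (0.0899 and 0.122). Of 21 glycolysis and hypoxia genes 4 fell and 0 rose, with the same counts adjusted over the list alone and a median of -0.07 (camera adjusted p = 0.0257, and adjusted p = 0.432 with an estimated correlation). Bnip3, a hypoxia-induced mitophagy gene, was at -0.55 ± 0.07. The calls of Egln3, Aldoc and Adm were less stable. Those of Egln3 and Aldoc ended without unstimulated replicate 1 (limma adjusted p = 0.0625 and 0.0589), and that of Adm without unstimulated replicate 2 (0.0806), among others. The list's call ended without unstimulated replicate 3 (0.0629), without estradiol replicate 3 (0.0556), with quantile normalization (0.0599) and with the filter on dim genes (0.0851). Its median was -0.02 without estradiol replicate 1, -0.04 without estradiol replicate 3, -0.045 without unstimulated replicate 1 and -0.11 with a common median.

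**Figure D1:**
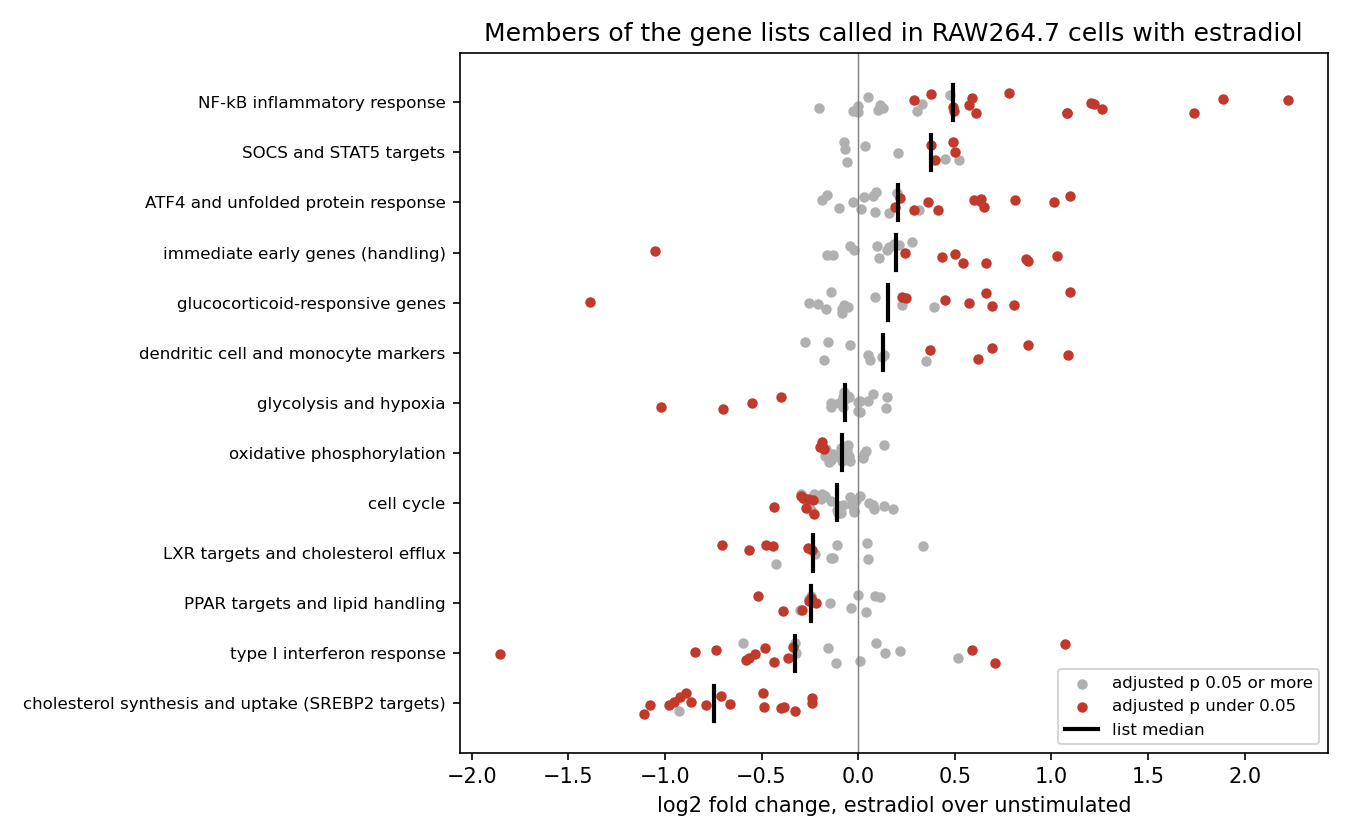
Log2 fold changes with estradiol in RAW264.7 cells of each measured member of the 13 called lists, with members at an adjusted p under 0.05 in red and a black line at each list's median. The cholesterol list lies furthest down, with a median of -0.75, and the NF-kB list furthest up, with a median of 0.49.

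Neuronal nitric oxide synthase, Nos1, fell with estradiol by 1.75 ± 0.10 on the log2 scale, from 6.88 in unstimulated cells (3.36-fold lower, limma adjusted p = 0.000174). It was dim, at 0 of 6 arrays above the 40th percentile, and the other Nos1 probe set changed by -0.21. Endothelial Nos3, also dim, fell by 0.35 ± 0.08 (adjusted p = 0.0343). The Nos3 call ended without unstimulated replicate 1 (adjusted p = 0.121), replicate 2 (0.0861), replicate 3 (0.110) or estradiol replicate 1 (0.0720), and in one fit of all 12 arrays (0.0829). Inducible Nos2, the form macrophages make when activated, had a change of -0.18 ± 0.12 that did not pass (adjusted p = 0.382). In the nitric oxide and arginine list of 15 genes, 2 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.590, and adjusted p = 0.0370 with fry).

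Receptors and classic targets of estrogen were not called as lists. Esr1 (0.10 ± 0.07), Esr2 (-0.01 ± 0.05) and the progesterone receptor Pgr (0.10 ± 0.18), all dim, did not pass (limma adjusted p = 0.406, 0.939 and 0.763). Of the 9 measured steroid receptors limma called 0, over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05, and the list's camera adjusted p was 0.694. Of 20 classic estrogen-regulated genes 2 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.876), against 1414 called of all 12393 genes. Cyclin D1, Ccnd1, rose by 0.42 ± 0.06 and the secreted hormone Stc2 fell by 0.61 ± 0.08.

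**Figure D2:**
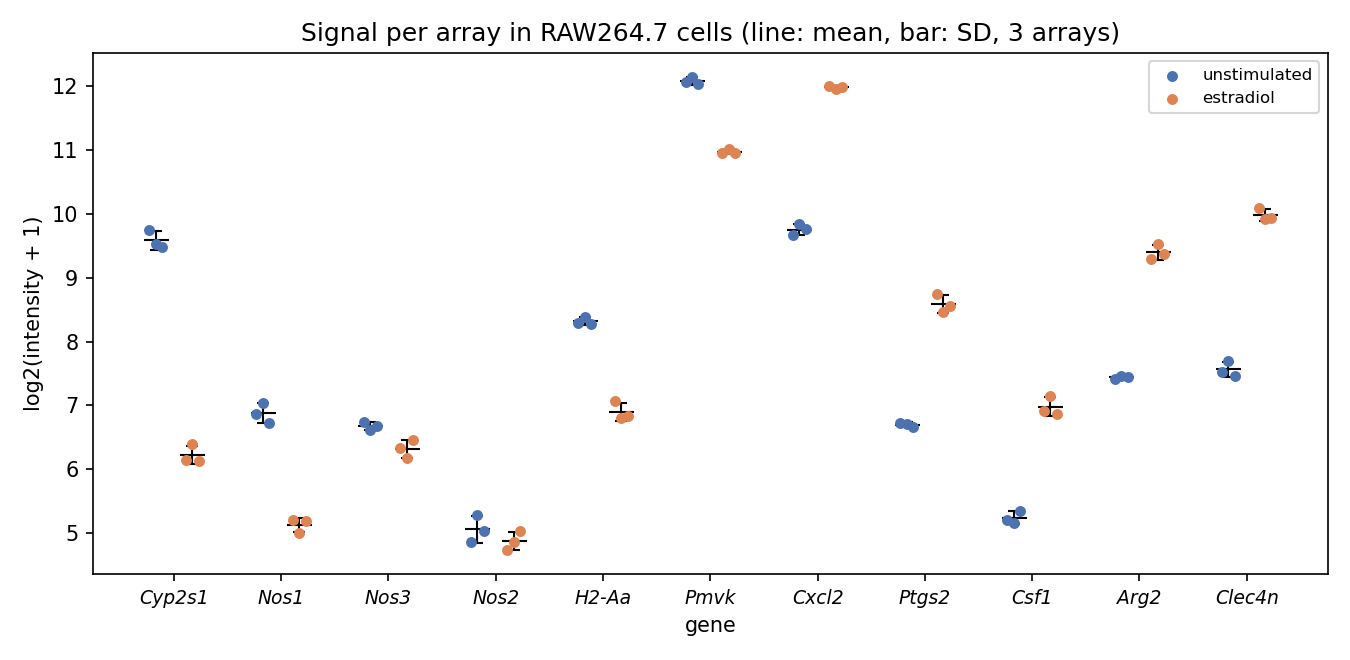
Log2(intensity + 1) of 11 genes on each RAW264.7 array, unstimulated or with estradiol, with a line at the group mean and a bar of 1 SD. Cyp2s1 has the largest fall (-3.36) and Clec4n the largest rise (2.42) among the genes drawn.

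Over all 12393 genes, limma called 1414 in this comparison, 836 higher and 578 lower, of which 76 and 30 passed 2-fold, and 3331 had an unadjusted p under 0.05. Groups did not overlap for 34.8% of genes, against 10% by chance. The median absolute log2 change of called genes was 0.39. With arrays shifted to a common median the split was 620 higher and 707 lower, so the excess of rises depended on scaling. The count was 681, 637 and 684 without unstimulated replicates 1, 2 and 3, and 824 without estradiol replicate 3. With array weights it was 4010. In one fit of all 12 arrays, calls ended for Ptgs2 (adjusted p = 0.0903), Ddit4 (0.0602), Ier3 (0.204), Fabp4 (0.101), Cdc20 (0.233), Cxcl10 (0.0617) and Ccnd1 (0.0830).

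With the 6 lavage arrays, no single gene passed the threshold between 3 pregnant and 3 control samples of lavage macrophages. The smallest adjusted p belonged to the hypoxia-responsive gene Ndrg1, which was higher by 0.75 ± 0.06 (log2, limma adjusted p = 0.115). Phlda3, a p53-induced gene, was 2.23-fold higher (1.16 ± 0.14), and the lipid carrier Fabp4 and caveolin Cav1 were higher by 0.79 ± 0.11 and 0.59 ± 0.07. Phxr4 and the basement membrane gene Nid2 were lower, at -1.56 ± 0.16 and -0.80 ± 0.11. Bex2 (0.81), Tmcc2 (0.91), Rtl6 (0.58) and the potassium channel gene Kcnj14 (0.48) complete the 10 smallest p-values, none past the threshold with the 6 lavage arrays, and Nid2, Bex2 and Kcnj14 were dim. In one fit of all 12 arrays 7 of them passed, with adjusted p = 0.0012 for Ndrg1, 0.0043 for Phxr4, 0.0059 for Phlda3 and Fabp4, 0.0136 for Bex2, 0.0167 for Tmcc2 and 0.0256 for Nid2. That fit left the log2 changes as they were and shared 1 spread per gene between lavage and cell-line arrays. The 2 sources may vary differently, so these smaller p-values may rest on the spread of the cell line.

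The nitric oxide synthases showed differences smaller than their errors in pregnancy, with Nos1 at 0.10 ± 0.14, Nos2 at -0.02 ± 0.12 and Nos3 at -0.00 ± 0.13 (limma adjusted p = 0.844, 0.968 and 0.994). Esr1 (0.00 ± 0.09), Esr2 (0.18 ± 0.09) and Pgr (0.00 ± 0.09) did not pass either (adjusted p = 0.997, 0.583 and 0.996), and all 6 genes were dim. In the nitric oxide and arginine list 12 of 15 genes had positive values, with 0 called by limma over all genes, 1 adjusted over the list alone and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0844).

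Between the 35 lists, camera called 2 in pregnancy, cell cycle genes upward and T cell markers downward. Cell cycle genes had positive values for 30 of 31 members, with a median of 0.28 (camera adjusted p = 1.3e-05, but adjusted p = 0.848 with an estimated correlation and 0.429 with fry). The mitotic kinase genes Bub1 (0.58 ± 0.18), Aurkb (0.49 ± 0.17) and Cdk1 (0.37 ± 0.14) and the spindle gene Tpx2 (0.42 ± 0.14) led by p. By limma 0 members passed over all genes or adjusted over the list alone, with 7 at an unadjusted p under 0.05. T cell markers had negative values for 13 of 15 members, with a median of -0.40 (camera adjusted p = 1.3e-05, but adjusted p = 0.688 with an estimated correlation and 0.429 with fry). Cd247, a chain of the T cell receptor complex, was at -1.17 ± 0.27, Thy1 at -1.11 ± 0.34, Cd28 at -0.96 ± 0.29 and Cd5 at -0.56 ± 0.17, and 0 members passed on either adjustment, with 4 at an unadjusted p under 0.05. The T cell markers named were dim, and under the filter on dim genes fewer than 5 of the list remained, so that it was not tested. Single arrays moved both medians. Without control replicate 1 they were -0.15 for T cell markers and 0.15 for cell cycle genes, without control replicate 3 the T cell median was -0.66, and without pregnant replicate 3 the cell cycle median was 0.16. With array weights the T cell median was -0.22. Control replicate 1 also had the highest mean of the lavage arrays for the NF-kB list, 9.51 against 8.73 and 8.68 in the other control and 8.62 to 9.28 in the pregnant samples, and for immediate early genes, 10.89 against 10.48 in both other control and 10.50 to 10.69 in the pregnant samples.

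Per array, the list means of the groups overlapped. T cell markers averaged 6.57, 6.47 and 5.82 in control samples and 5.72, 5.86 and 5.67 in pregnant samples, a difference of -0.53 ± 0.24 (SE). Cell cycle genes averaged 9.72, 10.04 and 9.90 in control and 9.99, 10.08 and 10.39 in pregnant samples, a difference of 0.26 ± 0.15. An exact two-sided permutation test of the means gave p = 0.2 for each, where 3 against 3 samples can reach 0.1 at the least. B cell markers differed by -0.11 ± 0.10 and NK cell markers by -0.13 ± 0.19, and neither list was called (camera adjusted p = 0.191 and 0.0935). Dendritic cell and monocyte markers differed by -0.26 ± 0.32 and platelet and megakaryocyte markers by 0.18 ± 0.03. These 2 lists were not called either (camera adjusted p = 0.0844 and 0.0909). Markers of airway and alveolar epithelium differed by 0.37 ± 0.46 (camera adjusted p = 0.462).

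**Figure D3:**
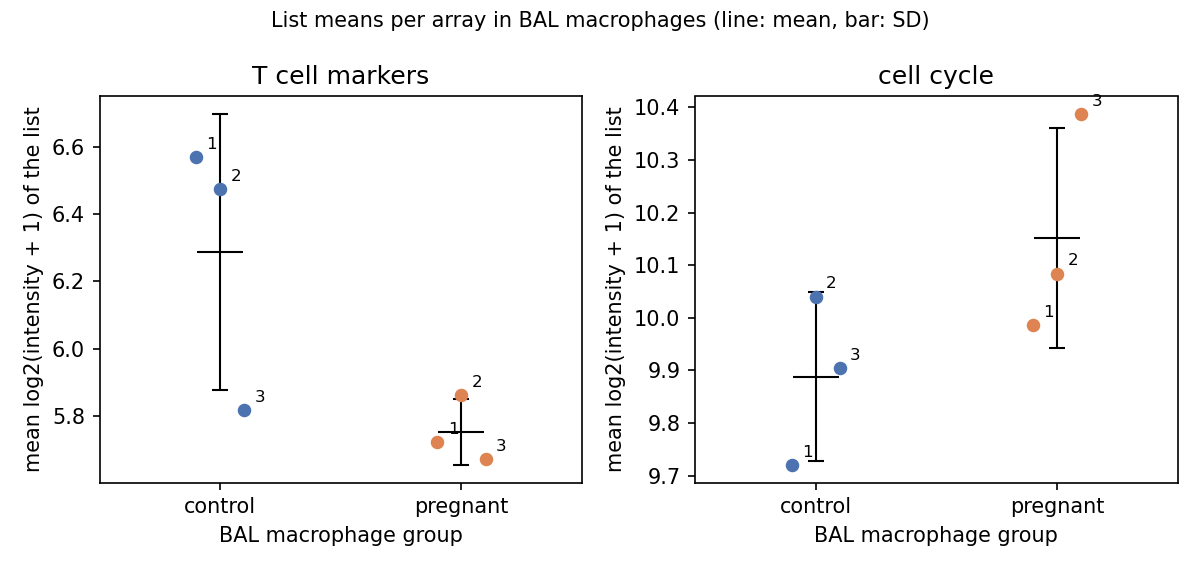
Mean log2(intensity + 1) of the T cell marker and cell cycle lists on each lavage array, numbered by replicate, with the group mean and a bar of 1 SD. Control replicate 3 (5.82) lies within the range of the pregnant samples (5.67 to 5.86) for T cell markers.

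Limma called 0 of 12393 genes in pregnancy, with 1163 at an unadjusted p under 0.05. Groups did not overlap for 15.7% of genes, against 10% by chance. The filter on dim genes gave 1 call (Ndrg1, adjusted p = 0.0391), the fit of all 12 arrays 18 (12 higher and 6 lower), and leaving out control replicate 1 gave 2, while every other setting gave 0. The number of called lists was 8 without control replicate 1, 9 without control replicate 3, 8 without pregnant replicate 2 and 8 without pregnant replicate 3. It was 0 with an estimated correlation or fry, and 4 with the filter on dim genes.

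At baseline, control lavage macrophages differed from unstimulated RAW264.7 cells in most genes, with culture, animal, sex-linked transcripts and cell type differing together. Chil3, a chitinase-like protein of alveolar macrophages, was higher in lavage cells by 10.14 ± 0.10 on the log2 scale, and Siglecf, a lectin of alveolar macrophages, by 8.99 ± 0.17. Plet1 (9.51), Tgfbi (9.35), the formyl peptide receptor Fpr2 (9.27), Acaa1b (9.07), P2ry14 (8.98), Mgst1 (8.94), Perp (8.90) and the glycogen phosphorylase Pygl (8.70) were also among the 10 largest rises. Lower in lavage cells were Y-linked Eif2s3y (-8.77), the transporter Slc6a12 (-8.36), Cadps (-8.30), Phyhipl (-8.28), Cldn11 (-8.25), the amino acid transaminase Bcat1 (-8.15), Ifitm6 (-8.04), Ndrg4 (-7.79), Pcdh7 (-7.73) and Fam13c (-7.20).

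Of 19 alveolar macrophage identity genes, 17 were higher and 0 lower in lavage cells, with the same counts adjusted over the list alone. All 31 cell cycle genes were lower (31 adjusted over the list alone), as were 16 of 18 cholesterol synthesis genes (17 adjusted over the list alone). Markers of airway and alveolar epithelium were higher in 21 of 23 cases and lower in 0 (22 and 0 adjusted over the list alone), including the club cell protein Scgb1a1 (7.44) and surfactant protein Sftpc (4.28). MHC class I genes were higher in 9 of 11 cases and lower in 0, with the same counts adjusted over the list alone. No list test was run in this comparison, and the size of a difference is approximate where one source lies near the lowest intensities. Limma called 7671 genes, 3462 higher and 4209 lower in lavage cells, of which 1320 and 1100 passed 2-fold.

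The 2 changes, estradiol in the line and pregnancy in lavage cells, were then compared directly, as the change in pregnancy minus the change with estradiol. Stimulus, cell source and culture differ together in this contrast, so a difference cannot be credited to the stimulus alone. Cyp2s1 differed by 2.92 ± 0.20 (limma adjusted p = 2.7e-05), with -3.36 with estradiol and -0.44 in pregnancy. Clec4n (-2.42 ± 0.12), Sulf2 (-2.34 ± 0.14) and Celf4 (-2.65 ± 0.26) rose with estradiol and had pregnancy values of 0.00, -0.06 and 0.07. The costimulatory receptor Tnfrsf9 differed by -1.89 ± 0.29, H2-Ea by 1.93 ± 0.33 and Ms4a4c by 1.89 ± 0.33.

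Cxcl2 differed by -2.19 ± 0.43 (limma adjusted p = 0.0183, and 0.0518 without unstimulated replicate 1). The matrix protease Mmp9 differed by -2.34 ± 0.48 (adjusted p = 0.0215), and the call ended without unstimulated replicates 1, 2 and 3 (0.0532, 0.0628 and 0.0554) and without estradiol replicates 1 and 3 (0.0519 and 0.0552). Rtp4 differed by 2.12 ± 0.44 (adjusted p = 0.0238), and its call ended without unstimulated replicates 1 and 2 (0.0659 and 0.0698), estradiol replicate 3 (0.0621) and control replicates 2 and 3 (0.0537 and 0.0544). Limma called 549 genes as differing, 274 with a positive and 275 with a negative value of the pregnancy change minus the estradiol change. This count was 276, 263 and 272 without unstimulated replicates 1, 2 and 3, 330 and 280 without estradiol replicates 1 and 3, and 1394 with array weights.

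No gene was called in both comparisons, since limma called 0 in pregnancy (1163 at an unadjusted p under 0.05). Across genes, the log2 changes with estradiol and in pregnancy had a Pearson r of 0.04 and a Spearman rho of 0.02, with genes not being independent replicates. Of the 1414 genes called with estradiol, 692 (48.9%) had the same sign in pregnancy. Leaving out 1 array moved rho between -0.087 and 0.107.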

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

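Among the tests below, those of RNA quality, endotoxin, handling, T cells, dividing lymphocytes and single arrays were chosen only after the results they weigh were seen, and the counts of other splits were planned. The test of single arrays in the lavage samples first asked only whether the calls held, which they did in 6 of 6 fits and which spoke against that explanation. It was replaced, after the medians without each array had been seen, by the test of size used for the estradiol lists, and the outcome turned with it. The tests of T cells and dividing lymphocytes first read the mean of the T cell list (-0.53 ± 0.24, SE), which spoke for the former and against the latter, and were replaced because that mean restates the fall and rests on dim genes.

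The change in pregnancy differed from the change with estradiol for 549 genes by a test of the difference itself. Stimulus, cell source and culture differ together between the 2 changes, so these genes cannot be credited to the stimulus alone. With 0 genes called in pregnancy, differences such as that of Clec4n (2.42 with estradiol and 0.00 in pregnancy) largely restate the estradiol change. The 10 named genes were Cyp2s1 (2.92), Celf4 (-2.65), Clec4n (-2.42), Mmp9 (-2.34), Sulf2 (-2.34), Cxcl2 (-2.19), Rtp4 (2.12), H2-Ea (1.93), Ms4a4c (1.89) and Tnfrsf9 (-1.89), as pregnancy minus estradiol in log2. Of 100 splits of the 12 arrays drawn, 3 gave as many genes, the real one included, and the highest other split gave 645. This share is under 0.05, but the count followed the grouping of the RAW264.7 arrays, so the share excludes chance for neither source. The 9 drawn splits that kept the RAW264.7 grouping gave 358 to 645 genes and the 91 others 0 to 16, but the cell line has only 10 groupings, too few for a share under 0.05. Of those 9 splits 3 gave as many genes, so chance is not excluded for the grouping of the lavage samples.

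Probe sets left out of the gene comparisons, because they were paired with no gene or with several, also carried signal. Of 2246 such probe sets limma called 157 with estradiol, 71 higher and 86 lower.

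The rise of the NF-kB list and the fall of the cholesterol synthesis list with estradiol were weighed against RNA quality, endotoxin and handling. Low 5' signal on estradiol replicate 2 does not carry the pattern, since without that array both lists kept their call and the smaller ratio of a median without it to that with it was 0.910, for the cholesterol list. Endotoxin in the estradiol, which would raise interferon genes with the NF-kB genes, is argued against as the whole cause by an interferon list mean of -0.21 ± 0.07 (SE), and of -0.43 ± 0.07 over its 13 members that were not dim, 11 of them lower. As a part of the cause it stays open, since 3 dim members rose (Gbp2 at 1.07, Gbp3 at 0.71 and Cxcl10 at 0.59), and the fall of the list was not called with an estimated correlation (adjusted p = 0.464) or fry (0.0532). A handling difference between cultures cannot be told apart from estradiol, because each culture condition holds 1 group. The same goes for solvent, unless the untreated cultures received vehicle, as the design text states and the label does not. The immediate early genes had a median of 0.197 that handling, solvent or estradiol may give, and an effect of estradiol remains open.

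Splits of the 6 RAW264.7 arrays were too few for a share under 0.05. The real split gave 1414 genes and 13 lists, 1 of 10 splits gave as many of each, and the highest of the others gave 0 genes and 9 lists. For control lavage against unstimulated RAW264.7 arrays the splits were again too few, with 7671 genes in the real split, 1 of 10 splits as large, and 0 in the highest other.

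The fall of T cell markers and rise of cell cycle genes in pregnancy were weighed against T cell content, dividing lymphocytes and single arrays. Single arrays may carry much of the size, since without control replicate 1, which also had the highest NF-kB and immediate early means of the lavage arrays (9.51 and 10.89), the T cell median was 0.377 of its value (-0.15 against -0.40) and the cell cycle median 0.15 against 0.28, although both lists kept their camera call at the preset correlation in 6 of 6 fits with 1 array left out. Fewer T cells in the lavage of pregnant mice and dividing lymphocytes both stay open, since 1 of the 15 T cell markers was not dim, too few to decide either. An effect of pregnancy on cell division stays open as untested. Splits of the 6 lavage arrays were too few for a share under 0.05, with 0 genes and 2 lists in the real split, as many genes in 10 of 10 splits and as many lists in 8 of 10, and up to 5 genes and 15 lists in the others.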

How the results depend on the processing

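The fit without a pseudocount was chosen after seeing the data, and the other alternatives were planned. With estradiol, limma's 1414 genes became 4010 with array weights, 106 at 2-fold or more, 558 at an adjusted p under 0.01 and 637 to 1730 with 1 array left out, of which 616 to 1269 were among the 1414. Other settings gave 1090 to 2098. In pregnancy the 0 genes (1163 at an unadjusted p under 0.05) became 1 with the filter on dim genes, 18 in one fit of all 12 arrays and 0 to 2 with 1 array left out. Between sources the 7671 became 13832 over all probe sets, which tests more features, and 2420 at 2-fold or more. The 549 genes of the difference became 1394 with array weights, 103 at 2-fold or more, 169 at an adjusted p under 0.01 and 263 to 573 with 1 array left out. Stricter thresholds lower counts by construction, and the cause of the other moves was not tested.

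Of the 13 lists called with estradiol, 2 held with an estimated correlation and 10 to 13 lists were called with 1 array left out. Fry called 16 lists with estradiol, 11 upward and 5 downward, without the interferon and cell cycle lists (adjusted p = 0.0532 each). Among the 16 were lists that camera did not call. These were neutrophil markers (fry adjusted p = 0.000177), heat shock (0.0047), NRF2 (0.00949), phagocytic receptors (0.0139) and nitric oxide (0.0370). Since fry does not compare a list with other genes, these calls show no shift particular to the lists. The phagocytic list, upward by fry, pointed down in camera (adjusted p = 0.972). Of the 2 lists called in pregnancy, 0 held with an estimated correlation or with fry. The number of lists there was 4 with the filter on dim genes and 2 to 9 with 1 array left out, and the cause was not tested. The rho of the 2 changes stayed within 0.154, its jackknife SE, of 0.021 in all settings run. That SE comes from the same fits with 1 array left out, so this was no separate check. In those fits rho lay between -0.087 and 0.107.

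None of the 88 named genes called with estradiol changed direction, and 51 were called in all settings where they were tested (115 of 1129 values fell short of the threshold). The kept direction says little, since all 1414 called genes had groups that did not overlap. Leaving out 1 array could therefore not turn a sign, and neither could settings that keep the log2 changes, such as the robust prior. All 23 named genes of the source comparison kept their call, as did 7 of the 10 of the difference. In pregnancy, Esr1 became -0.0408 with quantile normalization, -0.0512 with a common median and -0.0378 with array weights, and Pgr became -0.0389, -0.0507 and -0.0039. With 1 array left out, Esr1 lay between -0.0597 and 0.0694, Pgr between -0.0597 and 0.0746, Nos1 between -0.018 and 0.228, Nos2 between -0.128 and 0.0662 and Nos3 between -0.114 and 0.106. With estradiol, Esr2 lay between -0.0288 and 0.0147 and Pgr between -0.118 and 0.218. None of these values passed the threshold, all were on dim probe sets, and the cause was not tested. The named nitric oxide synthases and sex steroid receptors were dim, as were the T cell markers named in pregnancy, and without detection calls their presence cannot be judged here.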

Other observations

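The MHC class II genes and the p53 question were chosen after values had been seen, as was the p53 test without members of other lists, but the p53 targets tested were listed before their own estradiol and pregnancy values were looked at.

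MHC class II genes split with estradiol in RAW264.7 cells. The chains that bind peptide fell, H2-Aa at -1.42 ± 0.08, H2-Ab1 at -0.95 ± 0.06 and H2-Eb1 at -0.55 ± 0.11 (log2 ± SE, limma adjusted p = 0.000183, 0.000277 and 0.0228). The peptide-loading chain H2-DMa (0.56 ± 0.06), the invariant chain Cd74 (0.27 ± 0.05) and the costimulatory molecules Cd80 (0.72 ± 0.09) and Cd86 (0.55 ± 0.13) rose. Apart from H2-Aa and H2-Ab1, these genes were not rerun under the alternatives. Over the 12 measured members 4 rose and 3 fell (4 and 4 adjusted over the list alone), the median was 0.05 and the mean -0.08, and camera, which pointed down, did not call the list (adjusted p = 0.733). Camera called neither neutrophil nor T cell markers as lists, while fry called the neutrophil markers upward (adjusted p = 0.000177). Of 12 neutrophil markers 2 rose and 0 fell, with the same counts adjusted over the list alone, and of 15 T cell markers 1 fell and 0 rose (2 and 1 adjusted over the list alone) (camera adjusted p = 0.389 and 0.526). The calprotectin subunit S100a8 rose by 1.74 ± 0.14 and the protease Mmp9 by 1.58 ± 0.06, while the costimulatory receptor Cd28 fell by 1.15 ± 0.10. Among antioxidant genes the cystine transporter Slc7a11 rose by 1.04 ± 0.06, a call that ended in one fit of all 12 arrays (adjusted p = 0.123), and of 16 heat shock genes 1 rose, Hspa1b, by 1.65 ± 0.14.

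In pregnancy the epithelial gene Epcam was higher by 0.88 ± 0.16 but did not pass (limma adjusted p = 0.395). Of the 23 measured epithelial markers 17 had positive and 6 negative values. Limma called 0 of them over all genes and 1 adjusted over the list alone (camera adjusted p = 0.462).

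Phlda3 (1.87), Fas (1.69) and Trp53inp1 (1.33), which p53 is known to induce, stood among the larger rises with estradiol, and it was asked whether other p53 targets rose too. Of 31 further targets, 29 were measured, and their median log2 change was 0.374 (camera adjusted p = 3.0e-07 over the 2 comparisons tested, and adjusted p = 0.00891 with an estimated correlation). Of these, 18 were called higher and 1 lower, among them Epha2 at 1.04 and Ercc5 at 0.93. Without Ddit4 and Sesn1, which are also in other lists whose totals were known by then, 17 of 27 were called higher and 1 lower (median 0.374, camera adjusted p = 3.0e-07, and adjusted p = 0.00926 with an estimated correlation). A p53-like response to this dose may therefore be part of the change, as a hypothesis, and DNA damage or cell stress was not measured. Cdkn1a, Sesn2, Ddit4 and Btg2, named earlier under other lists, also belong to the p53 targets written down, so these lists share members. In lavage cells Phlda3 was among the smallest p-values of the pregnancy comparison, and the same 29 genes had a median of 0.0438 (camera adjusted p = 0.863), which does not decide the question.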
